A study of Mus musculus with 12 samples.

How the data were processed

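RNA from basolateral amygdala neurons of mice given footshocks (shock) or exposed to a female mouse (female) was measured on 6 Affymetrix mouse expression arrays, 3 per group, each deposited as an RMA and as a MAS5 sample. The authors deposited RMA values on the log2 scale, per the submitters' processing notes, and MAS5 intensity values on the linear scale, per the same notes and the values themselves. Software, versions and the scaling target of MAS5 are not given in the sources used here. The authors also deposited a comparison table for each processing, whose headers name group averages in log2, standard deviations, a signed linear fold change of female against shock (a score that is negative where shock is higher), and an ANOVA p-value with an FDR p-value, per the file headers. The deposited group averages lay close to the median of the 3 arrays, with a median difference of 0.01 (log2) in both groups on RMA values. Probe sets were named, and positions given, from these tables. The files name no genome build, and positions are printed as they stand there.

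Of 45101 probe sets, 64 controls were set apart, and 45037 remained, of which 38130 had 1 gene symbol, 1253 several and 5654 none. Symbols of 87.0% of those with 1 symbol were found in the reference gene table (assembly GRCm38.p6), which was used for names and synonyms. The main comparison was shock minus female on the RMA values with group as the only term, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), on the 27022 probe sets whose mean RMA value lay above the 40th percentile (6.31). Adjusted p is Benjamini-Hochberg over all tested probe sets, 2-sided, with a threshold of 0.05. Every p and adjusted p of a gene or probe set in the text is from limma unless it is called exact or the authors'. A gene was represented by its probe set with the highest mean RMA value, and an _x_at probe set was used only where there was no other. Lists of genes were written before the data were examined, from general knowledge of the tissue, and 28 with at least 5 tested members were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry in 1 direction were alternatives, and no list passed with either. The mixed form of fry, which asks whether members change in either direction, was not counted as an alternative. Its adjusted p was under 0.05 for 23 of the 28 lists, and was 0.120 for the oligodendrocyte list. Of 888 listed genes, 834 matched a probe set, 4 of them through a synonym.

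Named genes are the 12 with the largest change in each direction among those with an adjusted p under 0.05 and no overlap of the groups, genes fixed in advance (Rspo2, Ppp1r1b, Fos, Pabpc1, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty), and up to 4 tested members of each list with the smallest p. Predicted gene models and probe sets without a symbol were not named, and some genes that the rule takes are left unnamed in the text. For 4 lists (blood cells, choroid plexus and ependyma, hippocampal neurons, heat shock) counts were given without members, a choice made after the values were seen. Genes named in the closing part and in no list rule above were also chosen after their values were seen, as were the list of interferon-stimulated genes, the 5' to 3' signal as a covariate, and the probe set nearest the 3' end as a representative. The main design, the other lists and the other alternatives were fixed before the data were examined.

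The 5' to 3' signal of an array is the median, over genes, of the most 5' minus the most 3' tested probe set, for probe sets 500 to 20000 bases apart. MAS5 values entered as log2(value + 16), with log2(value + 1) as an alternative, so that fold changes of dim probe sets are understated. Other alternatives were no filter, a filter at the 60th percentile, a further quantile normalization, median centring, an intensity trend with a robust prior, array weights, the replicate number as a block, the mean of a gene's probe sets, the most variable probe set as representative, and leaving out each array. Exact permutation tests were 2-sided and cannot go below 0.1 with 3 against 3 arrays. The labels do not say whether pools of a group are from separate mice, so every test measures the spread between arrays.

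The steps were tested on simulated data for shock against female with 27022 probe sets, of which 200 were changed. The fit recovered 75% of changes of 1 (log2) and 14% of changes of 0.5, with 3 false among 92 calls, and made no call where nothing was changed. With 5404 changed, all by the same size between 0.5 and 1 (log2), it made 5100 calls, 4.22% of them false. The median size of a difference in the data was 0.22, so this does not show how many changes of that size would be found. A list shifted by 0.4 was called with no other of the 28 lists, and a 5' to 3' shift of -0.30 in 2734 genes was recovered as -0.30. Probe sets were drawn independently, so the simulation leaves out correlation between genes, which was estimated at 0.72 in the oligodendrocyte list. It does not measure the false calls that such correlation would give.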

Results

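Gene expression was measured in neurons of the basolateral amygdala (BLA), a brain region involved in learning about rewarding and aversive events, in mice given footshocks or exposed to a female. A FLAG-tagged form of PABPC1, a protein that binds the poly(A) tail of mRNA, was made there under the promoter of fos, a gene that neuronal activity switches on, and RNA was recovered by immunoprecipitation against the tag. Each of the 2 groups had 3 arrays (Affymetrix mouse expression arrays), and each array was deposited both as RMA and as MAS5 values, so that the 12 deposited samples are 6 arrays. The design note gives pools of 2 mice for a sample and 3 mice for a group, which leaves open whether arrays of a group share mice. Below, n is the number of arrays, and this number limits the precision of every value. The median RMA value of an array lay between 6.92 and 6.96 (log2) and the lower quartile of its MAS5 intensity between 38.5 and 55.6, highest in female replicate 2. Across probe sets, the arrays of a pair correlated at 0.991 to 0.993 within the shock group, 0.974 to 0.994 within the female group and 0.936 to 0.985 between the groups.

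The comparison of shock with female asks which mRNAs differ between BLA neurons that were active during an aversive and during a rewarding experience. Rspo2, which encodes a secreted enhancer of Wnt signalling, was 1.93-fold higher in shock, and Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, was 2.50-fold higher in female. The RMA value of Rspo2 (chromosome 15, positions 43020788 to 43021699, minus strand; the genome build is not given in the sources used here) was 7.65 ± 0.28 in shock and 6.71 ± 0.57 in female (log2, SD, n = 3), a difference of 0.95 with a standard error of 0.25 and a limma adjusted p of 0.0297. That of Ppp1r1b (chromosome 11, positions 98348692 to 98357794, plus strand) was 6.86 ± 0.18 in shock and 8.18 ± 0.77 in female (log2, SD, n = 3), a difference of -1.32 with a standard error of 0.30 and a limma adjusted p of 0.0198. For both genes all arrays of one group lay above all arrays of the other. From general knowledge of the study, and not from its labels or files, both genes were singled out on these samples, so their direction here is not independent evidence. Each lost its call when any 1 shock array was left out, with adjusted p of 0.124, 0.0548 and 0.105 for Rspo2 and 0.0920, 0.0574 and 0.0762 for Ppp1r1b without shock replicates 1, 2 and 3, although the differences stayed at 0.90, 1.11 and 0.84 and at -1.33, -1.40 and -1.23. Both kept the call when any 1 female array was left out. Without female replicate 2 the Rspo2 difference was 0.62 (adjusted p = 0.0132) and the Ppp1r1b difference -0.90 (adjusted p = 0.00335). On the MAS5 values the differences were 0.58 (adjusted p = 0.248) and -1.22 (adjusted p = 0.0776). With the 5' to 3' signal of each array as a covariate they were -0.016 and -0.25. In the authors' deposited table, which writes shock above female as a negative fold, Rspo2 had a fold of -1.68 with an FDR of 0.244 and Ppp1r1b a fold of 2.34 with an FDR of 0.220.

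The reporter's own genes did not pass the test. Fos was 0.36 (log2) higher in shock with an adjusted p of 0.0844 (0.21 without female replicate 2), and Pabpc1, whose probe set does not separate the tagged from the native transcript in the files, differed by 0.18 with an adjusted p of 0.513. The sign of Pabpc1 turned under array weights (-0.02) and without female replicate 2 (-0.09), and its difference was 0.35 without female replicate 1.

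**Figure D1:**
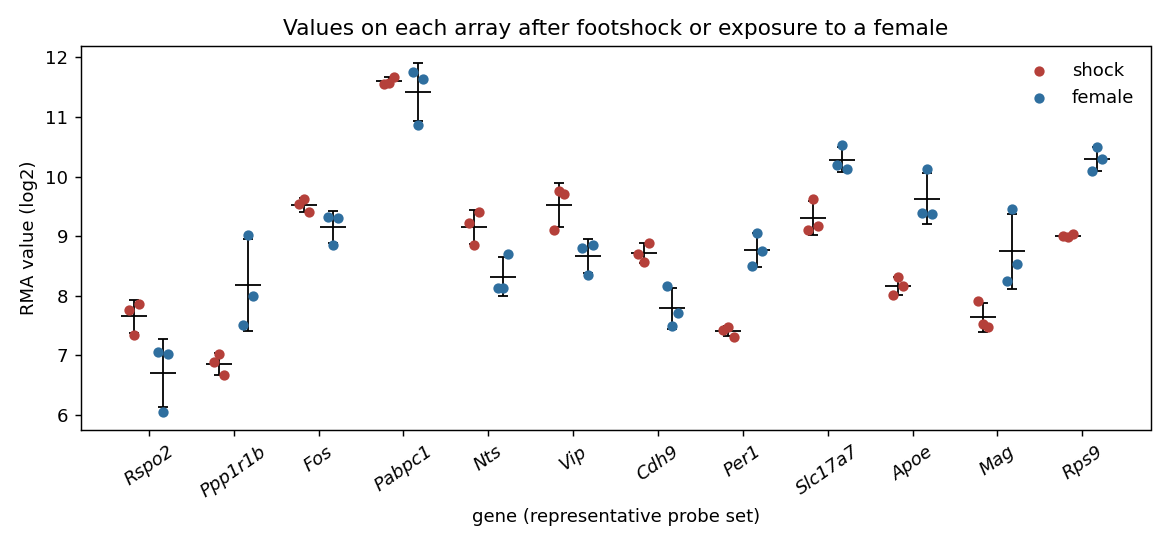
RMA values (log2) of 12 genes on each of the 3 shock and 3 female arrays, with black bars for the mean ± SD of the group. Rspo2, Fos, Nts, Vip and Cdh9 lay higher on every shock array, Ppp1r1b, Per1, Slc17a7, Apoe, Mag and Rps9 on every female array, and the arrays of the groups overlapped for Pabpc1.

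Shock and female samples differed at many transcripts, mostly by less than 2-fold. Of 27022 probe sets tested, 5614 differed, 2516 higher in shock and 3098 higher in female, and 180 of them differed at least 2-fold, 29 higher in shock and 151 higher in female. By gene, 1401 were higher in shock and 1241 higher in female among 13203 tested. Among genes whose groups did not overlap, the 12 with the largest rise in shock ran from Ptprc, the leukocyte phosphatase CD45, at 1.36 (log2, standard error 0.16, adjusted p = 0.00401) to Pcdh18, a protocadherin, at 0.97. Among them were 4 interferon-inducible genes, Gbp7 (1.24), Gbp6 (1.15), Trim30d (1.06) and Ifit2 (1.01), each called in 2 of the 6 fits that left out 1 array. Without shock replicate 2, Gbp7 was at 0.83 and Gbp6 at 0.64. The others were the activin-receptor gene Acvr1c (1.09), the protocadherin gene Pcdh8 (1.07), Moxd1 (1.06), the neurexophilin gene Nxph2 (1.05, and 0.61 without female replicate 2), Eya1 (1.00) and Dpyd (0.99). On MAS5 values Ptprc was at 0.78, Moxd1 at 0.66 and Dpyd at 0.30. By the same rule, and leaving aside symbols of unnamed clones, the 12 with the largest fall ran from Rabac1, which encodes a Rab GTPase acceptor, at -1.57 (log2, standard error 0.20, adjusted p = 0.00401) to Apbb1, which encodes a binding partner of the amyloid precursor protein, at -1.37. Between them lay Ldb1 (-1.50), the lipid carrier gene Apoe (-1.47), Ube2m (-1.45), the selenoprotein gene Sepw1 (-1.44, and -0.10 at a brighter probe set, not called), the clathrin adaptor gene Ap2s1 (-1.42), Haghl (-1.42), Prrc2a (-1.40), the mitochondrial import gene Timm13 (-1.39) and Rasl10b (-1.38). The remaining one, AY036118 (-1.43), has a symbol in the form of a sequence accession. Its values ran close to those of the 18S ribosomal RNA control probe sets, at 11.01 and 11.31 in shock replicate 3 and 13.75 and 13.88 in female replicate 2. Whether it measures ribosomal RNA was not tested.

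The number of differing probe sets depended on single arrays and on the processing. It was 321 without shock replicate 1, 1562 without shock replicate 2, 1312 without shock replicate 3 and 3628 without female replicate 3. It was 8752 with array weights and 543 on the MAS5 values, where 33 were higher in shock and 510 higher in female. When any 1 array was left out, 308 were called each time, 30 higher in shock and 278 higher in female. All 5614 kept their sign, but they were chosen for a difference on these same arrays. Where the groups do not overlap, leaving out 1 array cannot turn the sign, so the kept sign is no test of stability. At an unadjusted p under 0.01 there were 5526 probe sets, against 270.2 given by chance on average, and the groups did not overlap at 47.7% of tested probe sets, against 10% by chance. Both chance values are averages. Probe sets vary together between arrays, so these averages do not give the spread of such counts and are no test.

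The position of a probe set along its transcript went with its direction. In 2734 genes with separate 5' and 3' probe sets, the 5' one had the lower log2 fold change in 78.2%, with a median difference of -0.29 (quartiles -0.52 and -0.03). The median log2 fold change was -0.12 at the 5' probe sets and 0.17 at the 3' ones. Of the 5' probe sets, 94 were called higher in shock and 492 higher in female, and of the 3' ones 407 and 171. Across these genes, which are not independent replicates, the fold changes at the 2 probe sets correlated at 0.313 (Pearson) and 0.285 (Spearman). In 88 genes both probe sets were called in the same direction, against 38 in opposite directions. In the control probe sets of Gapdh, the 3' signal exceeded the 5' signal by 4.43 ± 0.26 in shock and 3.00 ± 0.43 in female (log2, SD, n = 3). With the 5' to 3' signal of each array as a covariate, chosen after the data were examined, 1 probe set was called. The difference of Rspo2 was then -0.02 with a standard error of 0.19, and that of Ppp1r1b -0.25 with a standard error of 0.29. This signal shares 0.659 of its variance with the group, so the covariate also takes up differences between the groups that have another origin. Of 114 called named genes, 50 had another tested probe set, which was called in the same direction in 16 and in the opposite direction in 4 (Adarb2, Grik3, Pde10a and Nr3c1). It had the opposite sign in 25, among them these 4, Eya1, Camk2a, Slc17a6, Foxp2, Gnb4, Bcan, Aldoc, Trhr, Scn2b, Cacna2d1, Rab3a, Stx1a, Bsn, Sema5a, Cntn4, Dach1, Atp5g1, Uqcrq and Rps9, and in 31 no other probe set was called.

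**Figure D2:**
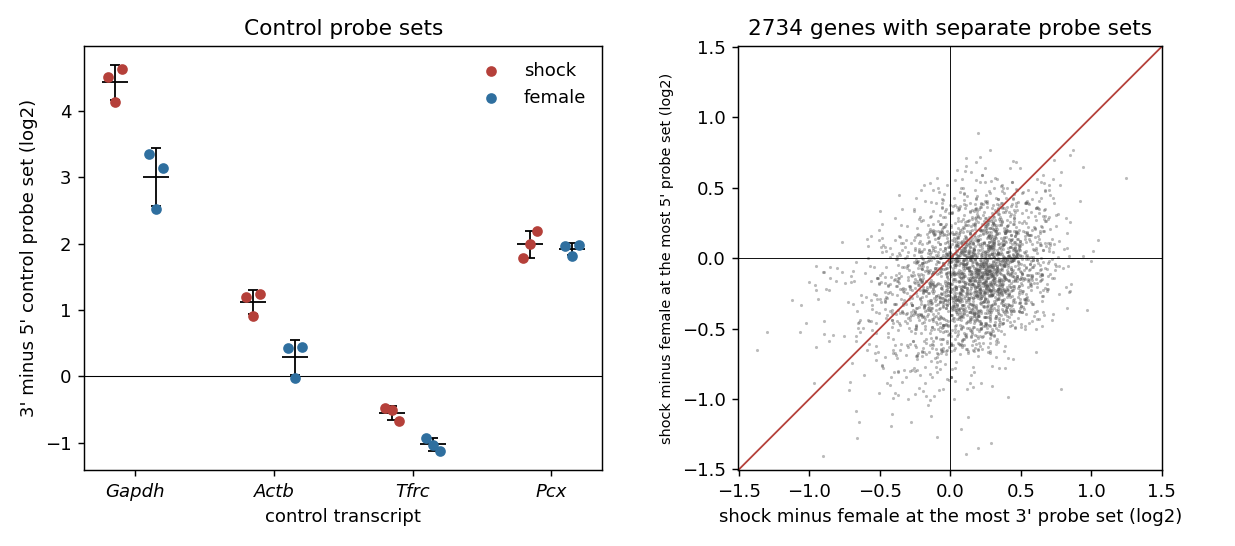
Left, 3' minus 5' control probe sets (log2) of 4 transcripts on each array, with black bars for the mean ± SD of 3 arrays; right, shock minus female (log2) at the most 5' against the most 3' probe set of 2734 genes, with equality as the red line. Gapdh and Actb lay higher on every shock array, Pcx overlapped, and 78.2% of genes lay below the red line.

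Genes of axon guidance and cell adhesion were shifted towards shock. Of 61 tested, 17 were higher in shock, 3 higher in female and 41 did not pass, and adjusted over the list alone 29 and 3 passed. The median was 0.38 (log2). The semaphorin gene Sema5a was higher in shock by 0.77, the contactin gene Cntn4 by 0.59 and the cadherin gene Cdh9 by 0.93, whereas the netrin receptor gene Unc5a was lower, at -0.69. The list passed camera (adjusted p = 0.000204) but not with an estimated correlation (p = 0.284, adjusted p = 0.929). It also lost the call with the 5' to 3' covariate (median 0.01, adjusted p = 0.384). With the most variable probe set as representative it lost the call too, though the median stayed as large (0.40, adjusted p = 0.0745). The median was 0.22 without female replicate 2 and also with the mean of a gene's probe sets. In female replicate 2 the median lay -0.41 from the other female arrays. Over all 10 splits of the 6 arrays into 3 and 3, each had as many lists past camera as the real one. The number of lists called therefore does not set these groups apart.

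Genes for ribosomal proteins and for mitochondrial oxidative phosphorylation were shifted towards female. Of 35 ribosomal protein genes tested, 14 were higher in female, 2 higher in shock and 19 did not pass (15 and 3 adjusted over the list alone), with a median of -0.19. Rps9 had a log2 fold change of -1.29, Rps19 of -0.79, Rpl18 of -0.74 and Rplp2 of -0.76. Other probe sets of Rps9 were at 0.02 and -0.08, neither called, and those of Rpl18 at -0.05, not called, and -0.94, called. Only 37 of the 65 listed genes had a probe set of their own symbol. Of 51 mitochondrial genes tested, 11 were higher in female, none higher in shock and 40 did not pass (11 and 0 adjusted over the list alone), with a median of -0.12 (-0.065 without female replicate 3). Among them, Uqcrq of complex III had a log2 fold change of -1.35 (0.12 at another probe set, not called), the ATP synthase genes Atp5g1 and Atp5e of -0.91 (0.29 at another probe set of Atp5g1, not called) and -0.63, and Cox6b1 of -0.55 (-0.17 at another probe set, not called). Camera gave adjusted p = 4.33e-05 for the ribosomal and 0.000204 for the mitochondrial list, and with an estimated correlation p was 0.0689 and 0.143 (adjusted p = 0.929 for both). Both camera calls held with the 5' to 3' covariate at the preset correlation (adjusted p = 0.00847 and 5.82e-06). The shifts were smaller in the more abundant members. In the 18 more abundant ribosomal genes the median was -0.13, against -0.33 in the 17 dimmer ones. In the 26 more abundant mitochondrial genes it was -0.045, against -0.24 in the 25 dimmer ones.

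Markers of oligodendrocytes, of vessels and of microglia were shifted towards female. Of 21 oligodendrocyte genes, 20 had a log2 fold change below 0 and 3 passed, all higher in female and the same number adjusted over the list alone. These were the myelin genes Mag (-1.11) and Cnp (-0.81) and the transcription factor gene Olig1 (-0.63), while Opalin (-0.56, and -0.31 without female replicate 2) had an adjusted p of 0.0623. Of 17 endothelial and mural genes, 5 were higher in female and 12 did not pass (7 in female adjusted over the list alone), among them Bsg (-0.88), Myl9 (-0.82), the tight junction gene Cldn5 (-0.78) and the glucose transporter gene Slc2a1 (-0.37). Of 16 microglial genes, 4 were higher in female, 1 higher in shock and 11 did not pass (5 and 1 adjusted over the list alone). Among them were Laptm5 (-0.67, and -0.30 at a brighter probe set, not called) and Tmem119 (-0.42). The complement genes were C1qb (-0.74, and -0.33 and -0.30 at brighter probe sets, not called) and C1qc (-0.56). The medians of the oligodendrocyte, vascular and microglial lists were -0.26, -0.23 and -0.14, and without female replicate 2 the oligodendrocyte median was -0.12 and the microglial one -0.086. Camera gave adjusted p = 0.000526, 0.0107 and 0.0174, and with an estimated correlation p was 0.331, 0.187 and 0.274 (adjusted p = 0.929 for all). None of the 3 calls held with the 5' to 3' covariate (adjusted p = 0.582, 0.147 and 0.424). The microglial call was also lost without female replicate 2 (adjusted p = 0.165) and with the filter at the 60th percentile (median -0.078, adjusted p = 0.588). It was lost with a median as large or larger without shock replicate 3 (-0.17, adjusted p = 0.0535), with array weights (-0.14, 0.105), with the most variable representative (-0.24, 0.130) and on MAS5 values (-0.21, 0.0786). The vascular call was lost with the filter at the 60th percentile (median -0.35, adjusted p = 0.0588) and with the representative nearest the 3' end (-0.18, 0.107). Oligodendrocyte genes in female replicate 2 had a median 0.39 above the other female arrays. Of 20 astrocyte genes, 5 were higher in female and 15 did not pass (5 in female and 2 in shock adjusted over the list alone), among them Apoe, Mlc1 (-0.64), Bcan (-0.79) and Aldoc (-0.56), and the list did not pass (median -0.08, adjusted p = 0.135). It passed towards female without female replicate 3 (0.0175), with a mean per gene (0.0253) and with the most variable representative (0.0123). The choroid plexus and ependyma list had 1 of 12 genes higher in female (0 adjusted over the list alone; median -0.14, adjusted p = 0.186).

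**Figure D3:**
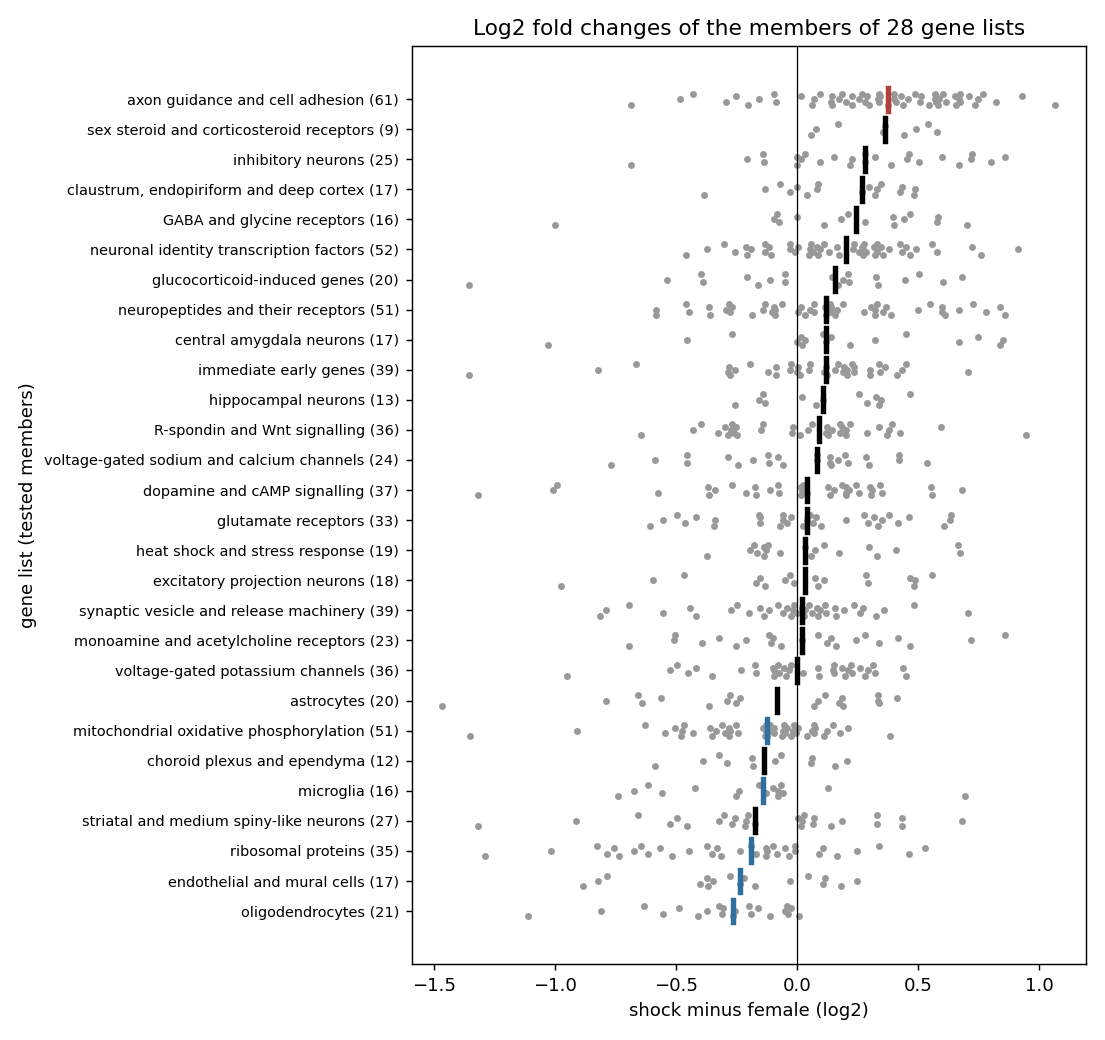
Shock minus female (log2) of each tested member (grey points) of the 28 gene lists with a list test, with the number of members in parentheses and a vertical bar at the median. Bars are red (higher in shock) or blue (higher in female) for the 6 lists that passed camera with a preset correlation and black for the others.

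Neuronal type markers went in both directions. Among 18 genes of excitatory projection neurons, the vesicular glutamate transporter gene Slc17a7 (-0.98), the kinase gene Camk2a (-0.47) and Nrgn (-0.60) were higher in female and the transporter gene Slc17a6 (0.49) and 1 other higher in shock (3 and 4 adjusted over the list alone), with a median of 0.03 and an adjusted p of 0.868. Among 25 inhibitory neuron genes, 7 were higher in shock, including the peptide gene Vip (0.86) and Adarb2 (0.50, with another probe set at -0.47 and an adjusted p of 0.0277), and the parvalbumin gene Pvalb (-0.69) was higher in female (8 and 1 adjusted over the list alone). Their median was 0.28 and the list did not pass (adjusted p = 0.0717), although it did on the MAS5 values (1.95e-05), without shock replicate 1 (0.00564), without female replicate 3 (0.0365), with the representative nearest the 3' end (0.0350) and without a filter on dim probe sets (0.0104). Of 27 striatal genes, 3 were higher in shock, including Pde10a (0.68) and Foxp2 (0.43), and 2 higher in female, Lrrc10b (-0.91) and Ppp1r1b, with the same counts adjusted over the list alone (median -0.17, adjusted p = 0.279). This list passed towards female without female replicate 1 (0.009996) and towards shock with the 5' to 3' covariate (median 0.11, adjusted p = 0.0229). The difference of Pde10a turned to -0.17 when its probe sets were averaged. Of 17 central amygdala genes, 4 were higher in shock, the peptide genes Nts (0.84) and Crh (0.67, and 0.43 without female replicate 2), the semaphorin gene Sema3c (0.75) and Calcrl (0.85, and 0.54 without that array), and adjusted over the list alone 4 were higher in shock and 1 in female (median 0.12, adjusted p = 0.440). Of 17 genes of the claustrum, endopiriform nucleus and deep cortex, 5 were higher in shock, including Synpr (0.48) and Gnb4 (0.35), with the same number adjusted over the list alone (median 0.27, adjusted p = 0.135, and 0.0390 without a filter). The hippocampal list had 1 of 13 genes higher in shock (0 adjusted over the list alone; median 0.11, adjusted p = 0.868), and the list passed towards female with the 5' to 3' covariate (median -0.28, adjusted p = 0.0229). Among 52 transcription factors of neuronal identity, 7 were higher in shock, including Tshz1 (0.91), Zfpm2 (0.76) and Dach1 (0.49), and 1 higher in female (5 and 1 adjusted over the list alone). Their median was 0.20 and the list did not pass (adjusted p = 0.133), although it did without female replicate 1 (0.0281) and without a filter (0.0104).

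Receptor, channel and release genes also went both ways. Of 36 genes of R-spondin and Wnt signalling, 4 were higher in shock, including Rspo2 and the R-spondin receptor gene Lgr4 (0.60), and 3 higher in female, including Dvl3 (-0.65) and Wnt2b (-0.43), with 2 and 3 adjusted over the list alone (median 0.09, adjusted p = 0.868). As Rspo2 is, on the same knowledge, one that the study chose on these samples, its part in this list is not independent evidence, and the same holds for Ppp1r1b in the striatal and dopamine lists. Of 37 genes of dopamine and cAMP signalling, 6 were higher in female and 3 higher in shock (6 and 3 adjusted over the list alone), with a median of 0.04 and an adjusted p of 0.868. Higher in female were, among others, the phosphatase gene Ppp1ca (-0.99), the kinase gene Cdk5 (-1.01, and -0.20 at another probe set, not called) and the phosphodiesterase gene Pde4a (-0.58). Of 33 glutamate receptor genes, 6 were higher in female, including Grik5 (-0.56), Grin2a (-0.46) and Cnih2 (-0.50), and 4 higher in shock, including Grik3 (0.61, with another probe set at -0.50 and an adjusted p of 0.0402), with 6 and 6 adjusted over the list alone (median 0.04, adjusted p = 0.868). Of 16 GABA and glycine receptor genes, 5 were higher in shock, including Glra2 (0.70), Gabra4 (0.44) and Gabrg1 (0.40), and Gabrd (-0.999, and -0.65 without female replicate 2) was higher in female, with the same counts adjusted over the list alone. Their median was 0.25 and the list did not pass (adjusted p = 0.135), although it did on the MAS5 values (0.0152). Of 51 genes for neuropeptides and their receptors, 5 were higher in shock, including Nts, Vip and the receptor gene Trhr (0.50), and 2 higher in female, including the vasopressin gene Avp (-0.58), with 4 and 1 adjusted over the list alone (median 0.12, adjusted p = 0.868). Of 23 monoamine and acetylcholine receptor genes, 3 were higher in female, Adra2c (-0.69), Hrh3 (-0.51) and Htr1b (-0.50), and 2 higher in shock, including Htr2c (0.47), with the same counts adjusted over the list alone (median 0.02, adjusted p = 0.588). Of 36 potassium channel genes, 6 were higher in female, including Kcnn1 (-0.53), Kcnip3 (-0.50) and Kcnc4 (-0.45), and none in shock, also adjusted over the list alone (median -0.0015, adjusted p = 0.682). Of 24 sodium and calcium channel genes, 3 were higher in female, including Scn2b (-0.77) and Hcn2 (-0.46), and 3 in shock, including Cacna2d1 (0.54), with the same counts adjusted over the list alone (median 0.08, adjusted p = 0.845). Of 39 genes of synaptic vesicles and release, 6 were higher in female, including Rab3a (-0.79), the syntaxin gene Stx1a (-0.81) and Bsn (-0.44), whose other probe sets were at 0.03 for Rab3a, 0.31 for Stx1a, and 0.23 and -0.56 for Bsn, with only the last called, and 2 in shock, with the same counts adjusted over the list alone (median 0.02, adjusted p = 0.520). With the most variable representative this list passed towards female (median -0.43, adjusted p = 0.0123).

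No list of activity, stress or steroid receptor genes passed the list test in the main fit. Of 39 immediate early genes, 3 were higher in female, the clock gene Per1 (-1.36), Dusp14 (-0.82) and Gadd45g (-0.67), and 3 in shock, including Nptx2 (0.71, and 0.44 without female replicate 2), with 3 and 0 adjusted over the list alone (median 0.12, adjusted p = 0.868). With the 5' to 3' covariate this list passed towards female (median -0.18, adjusted p = 0.00682). Of 20 glucocorticoid-induced genes, 3 were higher in female, including Per1 and the metallothionein gene Mt2 (-0.54), and 3 in shock, including Hif3a (0.68, but 0.015 on MAS5 values) and Pdk4 (0.60), with 4 and 4 adjusted over the list alone (median 0.16, adjusted p = 0.868). Of 9 steroid receptor genes and related genes, 2 were higher in shock, including the glucocorticoid receptor gene Nr3c1 (0.49), and 4 adjusted over the list alone, among which neither Pgr (0.36, adjusted p = 0.0642) nor Esr1 (0.44, adjusted p = 0.0763) passed over all genes. Without female replicate 2 their differences were 0.23 and 0.24. Their median was 0.36 and the list did not pass (adjusted p = 0.0717), although it did without female replicate 3 (0.0334) and without a filter (0.0314). The difference of Nr3c1 was -0.0024 when its probe sets were averaged. The heat shock list had 2 of 19 genes higher in shock and 1 higher in female (0 and 0 adjusted over the list alone; median 0.03, adjusted p = 0.868). For several uncalled lists, such as the immediate early genes, the median lay above 0 while camera ranked the members below the other genes, and in the lists of dopamine signalling, sodium and calcium channels and synaptic vesicles the mean (-0.02, -0.01 and -0.03) had the opposite sign to the median. Of the sex-linked genes, Ddx3y was 0.68 higher in shock (adjusted p = 0.0149), while Eif2s3y (0.33, and 0.19 without shock replicate 1), Kdm5d (-0.14) and Uty (-0.02) did not pass and the sign of Kdm5d and Uty turned under other settings. Xist was too dim to be tested, at 5.79 in both groups. None of the 3 tested blood cell genes passed, over all genes or adjusted over the list alone.

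The same scans processed with RMA and with MAS5 gave similar differences. Their log2 fold changes correlated at 0.837 (Pearson) and 0.835 (Spearman) across tested probe sets, and 98.6% of the probe sets with an unadjusted p under 0.01 on RMA values had the same sign on MAS5 values. Of the 543 probe sets called on MAS5 values, 483 were also called in the same direction on RMA values, and of 121 called named genes 37 were called on MAS5 values. The authors' deposited comparison holds 9931 probe sets with an unadjusted p under 0.05 on RMA values, 4379 higher in shock and 5552 higher in female, and none with an FDR under 0.05, the lowest being 0.0810. At an unadjusted p under 0.05 and at least 2-fold it holds 149, 19 higher in shock and 130 higher in female. On MAS5 values it holds 5767 at that p, with a lowest FDR of 0.147.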

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

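The measures and criteria of this part were chosen after the results they weigh were seen, although leaving out 1 array was an alternative fixed before. The control probe sets, which enter no comparison, gave 7 measures of RNA integrity, ribosomal RNA and added standards, and 4 separated the groups completely, which chance does for 10% of measures. The measures are not independent, since several give the 3' minus 5' signal of the same arrays, so the 10% is no test of this count. The 3' minus 5' signal was higher in shock than in female by 1.43 (log2) for Gapdh, 0.83 for Actb and 0.47 for Tfrc, each higher in 3 of 3 shock arrays. For Tfrc it was below 0 in both groups, with means of -0.55 in shock and -1.02 in female. The signal of 18S ribosomal RNA was 11.99 ± 0.59 in shock and 13.34 ± 0.50 in female (log2, SD, n = 3), a difference of -1.35. For each of the 4 the exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. The same measure of Pcx differed by 0.07 (exact permutation p = 0.6), and the hybridisation and poly-A standards differed by -0.23 and -0.06 (exact permutation p = 0.3 for both).

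The pattern weighed here is the large number of probe sets that differ between shock and female. A loss of 5' signal in the shock samples, from RNA degradation or shorter amplified products, may account for part of it, since the 5' probe set had the lower fold change in 78.2% of genes and the count was 1 with the 5' to 3' signal as a covariate. With that covariate the median size of a difference went from 0.22 to 0.14 (log2) and the median standard error from 0.12 to 0.16, so the calls ended through smaller differences and through lost precision. Female replicate 2 alone is argued against, as 5561 probe sets were called without it, and the 10 splits of the 6 arrays are too few for a share under 0.05, with 5614 probe sets called in the real split (1 of 10 with as many) and 0 in the highest other. A response of the neurons to shock or to a female stays open, since the 5' to 3' signal goes with the group in all 6 arrays.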

How the results depend on the processing

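The 5' to 3' covariate and the representative nearest the 3' end were chosen after the data were examined, the other alternatives before. Of 121 called named genes, 120 kept call and direction under a further quantile normalization, all 121 under median centring, the intensity trend, array weights and the replicate block, 111 without a filter, 37 and 24 on MAS5 values with 16 and 1 added, 94 with 1 mean per gene (25 lost, 2 reversed), 0 with the covariate (117 lost, 4 reversed), and 27 to 120 when 1 array was left out. With the filter at the 60th percentile all 94 still tested kept theirs. The counts of differing probe sets (5614) and of those at an unadjusted p under 0.01 (5526) were 543 and 2244 on MAS5 values with 16 added, 277 and 2115 with 1 added, 2499 and 2567 with 1 mean per gene (fewer values tested), 1 and 871 with the covariate, and 321 to 6756 and 2789 to 6204 without 1 array (fewer samples). Array weights gave 8752 of the first. Calls on MAS5 values were 6.08% higher in shock, against 44.8% on RMA values. Gene lists past the test (6) were 10 without a filter, 0 with an estimated correlation, 0 with fry in 1 direction, and 5 to 9 without 1 array. The correlation of RMA and MAS5 differences (0.837) was 0.725 without a filter, 0.882 with the filter at the 60th percentile, and 0.773 to 0.866 without 1 array. It was lower where dim probe sets, close to background, were kept. The 10 splits of the 6 arrays are too few for a share under 0.05, with 5526 probe sets at an unadjusted p under 0.01 in the real split (highest other 47, and 1 of 10 with as many). For the lists the limit is another, as 6 passed in the real split, 10 in the highest other, and 10 of 10 splits had as many. The number of lists that pass therefore does not set shock against female apart from other groupings of the arrays. Except where stated, the cause of a change was not tested.

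With the replicate number as a block, 7120 probe sets differed, 6354 had an unadjusted p under 0.01 and 6 lists passed. Whether the numbers pair the arrays was checked from the deviations of same-numbered arrays, which correlated at 0.01, 0.21 and 0.15 for numbers 1, 2 and 3. Samples 2 and 3 each correlated best with their own number, and those of number 1 did not, so whether same-numbered arrays belong together stays open.

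These log2 differences of named genes changed sign. Uty was 0.12 and 0.13 on MAS5 values with 16 and 1 added, 0.0050 after quantile normalization, 0.0047 after median centring, 0.14 with the covariate and -0.10 to 0.076 without 1 array. With array weights Pabpc1 was -0.020, Kdm5d 0.0061, Fibcd1 -0.59 and Spink8 -0.073. With the mean per gene Pde10a was -0.17, Nr3c1 -0.0024 and Aqp4 -0.16. Without 1 array Pabpc1 was -0.094 to 0.35, Fibcd1 -0.77 to 0.84, Spink8 -0.21 to 0.65 and Aqp4 -0.037 to 0.20. With the covariate Rspo2 was -0.016, Pabpc1 -0.49, Kdm5d 0.081, Nptx2 -0.024, Calcrl -0.033, Crh -0.042, Esr1 -0.033, Fibcd1 -2.45, Spink8 -1.04, Prkcd 0.13, Adora2a 0.20, Gja1 -0.0050 and Aqp4 -0.0085. The cause was not tested.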

Other observations

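The genes, the list and the comparisons of this part were chosen after their values were seen, although the main fit and leaving out 1 array were fixed before. Several genes that interferon induces were higher in shock. Of 26 tested, 6 were called higher in shock, none higher in female, and 22 had a difference above 0, with a median of 0.68 (log2), a camera p of 0.000288, and p = 0.379 with an estimated correlation. Beside Gbp7, Gbp6, Trim30d and Ifit2, the antiviral gene Rsad2 (1.59, adjusted p = 0.0304) and Trim30a (0.76, adjusted p = 0.0295) passed, while the chemokine gene Cxcl10 (1.71, adjusted p = 0.0996), Oasl2 (1.73, adjusted p = 0.0654), Ifit1 (1.62, adjusted p = 0.0511) and B2m (0.60, adjusted p = 0.0570) did not. Without shock replicate 2, Cxcl10 was at 0.88 and Oasl2 at 1.08. The list was drawn up after 11 of these genes had been seen among the largest changes, so its p-values are not independent evidence of a shift of the group. The other 15 had a median of 0.34 (camera p = 0.0667, and p = 0.524 with an estimated correlation), but they are also the 15 with the lowest differences, so leaving out the 11 lowered this value by construction.

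Female replicate 2 stood apart from the other female arrays, in single genes that mark parts of the brain near the BLA and in other groups. The RMA value of Fibcd1 there was 6.53, against 9.75 and 9.69 in female replicates 1 and 3, and that of Spink8 was 6.65, against 8.39 and 8.23, both markers of hippocampal pyramidal neurons. The kinase gene Prkcd, high in the lateral central amygdala, was at 9.07 there, against 7.33 and 7.77, and the striatal receptor gene Adora2a at 9.40, against 8.44 and 8.59. The 21 oligodendrocyte genes had a median 0.39 above that of the other female arrays, with none below, and the 13 tested hippocampal genes a median of -0.46. Lists that mark no region had similar medians, -0.41 for axon guidance and -0.38 for the immediate early genes. The 17 central amygdala genes did not follow Prkcd, with a median of -0.11 and 10 below 0, and of the 27 striatal genes, with a median of 0.29, 11 were below 0. The same array had the smallest 5' to 3' loss (5' minus 3' of -0.47, against -0.72 and -0.74), the lowest Gapdh 3' minus 5' signal (2.52, against 3.36 and 3.13), the highest 18S ribosomal RNA (13.88), and a score of 56.6 on the first principal component (73.1% of variance), against 9.11 and 15.7. Across probe sets, its difference from female replicate 3 correlated at -0.455 with the shock mean minus female replicate 1, and its difference from replicate 1 at -0.547 with the shock mean minus replicate 3. Groups of 3 arrays were not tested for outlying arrays, and no explanation was tested.

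In some genes the most 5' and the most 3' tested probe set were called in the same direction. Such probe sets can lie as close as 500 bases, so they need not sit at the 2 ends of a transcript. Whether these genes are free of the loss of 5' signal was not tested. There were 26 such genes higher in shock and 62 higher in female. Higher in shock were the kinase gene Riok2 (0.73 at the 5' and 0.85 at the 3' probe set, 927 bases apart), the calcium-binding protein gene Necab1 (0.64 and 0.94, 2684 bases) and the ephrin receptor gene Epha5 (0.61 and 0.79, 12468 bases). Higher in female were the GTPase gene Diras1 (-1.41 and -0.90, 1000 bases) and the drebrin gene Dbn1 (-0.65 and -1.37, 590 bases), an actin-binding protein of dendritic spines.

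The shift of oligodendrocyte genes towards female was the next pattern weighed, and a response of oligodendrocytes or of neurons to the stimulus stays open as untested. A lower share of neuronal RNA in the female samples, which would raise other cell types alike, may be the source and stays open. The more abundant astrocyte genes moved apart from the oligodendrocyte ones by 0.30 (log2, exact permutation p = 0.1, the smallest possible), with a median of 0.18 towards shock and 7 of 10 above 0, but by 0.17 without female replicate 2, and the called astrocyte genes and the vascular and microglial lists went towards female. More oligodendrocyte RNA carried through the immunoprecipitation in the female samples may also be the source and stays open, since the more abundant markers differed by -0.21 (-0.10 without female replicate 2) with overlapping groups (exact permutation p = 0.3), with Mbp at 13.03 in shock and 13.29 in female and Mobp at 12.37 and 12.74. The loss of 5' signal in shock may also contribute and cannot be told apart, because the markers' probe sets nearest the 3' end were lower in every shock array, by -0.45 against all genes (-0.24 without female replicate 2), while the list's median was 0.02 with the covariate, against -0.26 without it.

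The rise of several interferon-induced genes in shock was the last pattern weighed. Variation between samples that has nothing to do with the stimulus may account for it and cannot be told apart from a response, since in 20 of the 26 genes the shock and female arrays overlapped and female replicate 1 lay above shock replicate 1 in 18. Shock replicate 2 alone also stays open, as the median was 0.44 without it, 1 gene was then called, and shock replicate 1 lay below female replicate 1 (medians -0.17 and 0.02 around the mean of all arrays). A response to footshock is a hypothesis that 3 arrays per group do not settle.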
